A study of Drosophila melanogaster with 3 samples.

How the data were processed

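The series measured where a GFP-tagged form of Vnd lay on the genome of Drosophila melanogaster embryos. Vnd (ventral nervous system defective) is an NK-2 class homeodomain protein that patterns the ventral neuroectoderm. Per the labels, embryos of 0 to 24 h carrying a vnd-eGFP fusion were used, chromatin was sheared by sonication to 200 to 800 bp, and an antibody against GFP was used for immunoprecipitation and sequencing (ChIP-seq). There were 3 biological replicates, per the labels, and all 3 formed 1 group. No peak list from control chromatin or untagged flies was used here, so no comparison between groups was made.

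The files were peak lists on the dm6 assembly, per the deposited notes. For each replicate the authors gave a ranked list of all called peaks and a thresholded list that had passed an irreproducible discovery rate (IDR) filter, called on that replicate alone. A further 4 ranked and 4 thresholded lists were derived from all 3 replicates, per the deposited notes, and are called joint lists here. In 3 of the 4 ranked ones, however, most peaks of each member compared matched a single replicate's list. Which replicates each joint list rests on is not stated. Of the thresholded ones 1 is named conservative. The aligner, the peak caller, their versions and the IDR setting are not given in the sources used here. Each peak carries a scaled IDR score and a signal score, both the authors' deposited values, whose scale the sources used here do not state. The ranked lists also hold the deposited −log10 of the global IDR. The signal and scaled score were used only to describe, rank and filter peaks within their own list. Peak lists give no read counts, so the depth of each library is unknown and no interval that needs it is given.

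Peaks on the arms X, 2L, 2R, 3L, 3R, 4 and Y were kept. Arm lengths of the reference sequence were checked against the largest peak coordinates, and no peak ran past an arm's end. Consensus regions were the merged intervals of the 3 thresholded lists, sharing at least 1 bp, that held a peak of all 3 replicates. The position of a region was the mean of the replicates' strongest summits. Its rank was the mean, over replicates, of the peak's signal percentile within its own list, where 100 is the strongest. Coordinates are 1-based, on dm6.

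Overlap between replicates was set against 1000 random placements of each replicate's peaks on the same arm, with a one-sided permutation p. Positions were assigned, in this order, to a promoter (within 500 bp of the transcription start site, TSS, of any transcript of a protein coding gene), 5′ UTR, coding exon, 3′ UTR, intron or intergenic sequence. Genes came from the BDGP6.54 annotation of Ensembl release 115. The shares were compared with 1000 random placements on the same arm by a two-sided permutation test with Benjamini-Hochberg adjustment over the classes. For 1000 placements the smallest p is 0.001 one-sided and 0.002 two-sided.

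A gene's territory was its span with 5 kb upstream and 2 kb downstream, and a gene was counted as bound when a consensus position lay in it. A position can lie in the territory of several genes. Random lists drew genes singly, so for lists with neighbouring members the permutation p can be too small. Each of 18 gene lists was compared with 10000 random lists of the same size, matched on decile of territory length, by a two-sided permutation test with Benjamini-Hochberg adjustment over the lists. The smallest p this gives is 0.0002. Of the list members fixed at the start, 3 were not analysed here.

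CAAGTG, the core of the NK-2 class site, was searched on both strands within 50 bp of each position and in windows of the same size centred 500 bp upstream and downstream. For these windows, upstream and downstream mean lower and higher genome coordinates, whatever the strand of the nearest gene. The central and upstream windows were compared by the exact McNemar test. The comparison motifs were TAATTA, CAGGTAG, GAGAGA, CAGCTG, TATCGATA and ACAATG, with adjustment over the 7 motifs. All 6-mers, joined with their reverse complements, were compared between central and flanking windows by Fisher's exact test. Fisher's exact test, two-sided, also compared the motif share between classes of regions. Intervals for shares are 95% Wilson intervals and cover counting error only.

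The lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. Named were vnd, ind, Dr, Egfr, ac, sc and l(1)sc, the genes with the nearest TSS to the 15 regions of highest rank, the 5 genes with the most positions in their territory, and up to 4 members of each list with the highest ranked region. Up to 2 members of a list without a region could also be named. The result of 1 further gene named by the rule is not reported here. Genes named only as the owner of the TSS nearest to such a position were added after their values were seen. Alternatives were stricter peak filters, other overlap and consensus rules, the authors' conservative list, other promoter and territory definitions, other matching of random lists, other motif windows, and leaving out each replicate in turn. A filter at a global IDR of 0.01 was among them and removed 0 peaks, since the deposited lists already end there; a filter at 0.001 was added after seeing the data.

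The steps were written in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. They were tested on simulated data. CAAGTG written into 200 of 1400 random positions was recovered at 200 of them, with an exact McNemar p of 1.48e-23. Of 20 simulated gene lists made rich in bound genes, 20 passed the adjusted threshold of 0.05, and of 100 random lists 1 did. The enriched lists were longer than most lists tested here, and most of their members were bound. They do not show what the test can find in shorter lists, for weaker excesses or for lists bound less often.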

Results

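Binding of GFP-tagged Vnd was profiled by ChIP-seq in whole Drosophila melanogaster embryos collected from 0 to 24 h, in 3 biological replicates of 1 transgenic line. The thresholded lists held 2408, 1986 and 2131 peaks in replicates 1, 2 and 3. Of these, 2384, 1966 and 2124 lay on the main chromosome arms, a mean of 2158 ± 211 (SD, n = 3). The peaks had median widths of 384, 360 and 376 bp and together covered 694 ± 76.2 kb (SD, n = 3). The sequencing depth behind each list is unknown.

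The vnd gene itself (FBgn0261930, X, 582121 to 598151, dm6) was examined first, since it was planned as a check on the labels. It held 1 consensus position, at X 590638, inside the gene span and 404 bp upstream of one of its own TSSs. That region had a rank of 66.7 on a scale where 100 is the strongest. Within 50 kb on either side of vnd lay 5 consensus positions, as many as or more than at 96.1% of protein coding genes, against a median of 1 per gene. The single replicates had 8, 9 and 7 regions there, or 8 ± 1 (SD, n = 3). Apart from the vnd position, the 5 lay at the promoters of spdi (X 617620), CG13364 (X 625353), RpL36 (X 629543) and su(sable) (X 635780), where RpL36 encodes a ribosomal protein; spdi, CG13364 and su(sable) are named here only because they lay in this window. At this distance 92.4% of genes had fewer. Within 20 kb the count was 2, and 74.6% of genes had fewer. Without libraries of other lines, these counts cannot decide whether the labels are right.

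In the ranked lists, which hold all called peaks, the surroundings of vnd also stood apart outside promoters, a comparison added after seeing the data. The highest signal per 5 kb bin, taken over peaks outside promoters, had a median of 27.9, 30.3 and 26.5 within 50 kb of vnd in replicates 1, 2 and 3. The medians over all genes were 19.7, 21.2 and 20.1. The vnd value was above that of 99.8%, 99.96% and 99.6% of genes. The ranked lists held 84643, 126078 and 95350 peaks in replicates 1, 2 and 3. Of these, 2481, 2074 and 2201 had a global IDR of 0.01 or less, so most had not passed the filter. The values around vnd were also below the median signals of the thresholded lists, 87.0, 86.2 and 81.7.

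**Figure D1:**
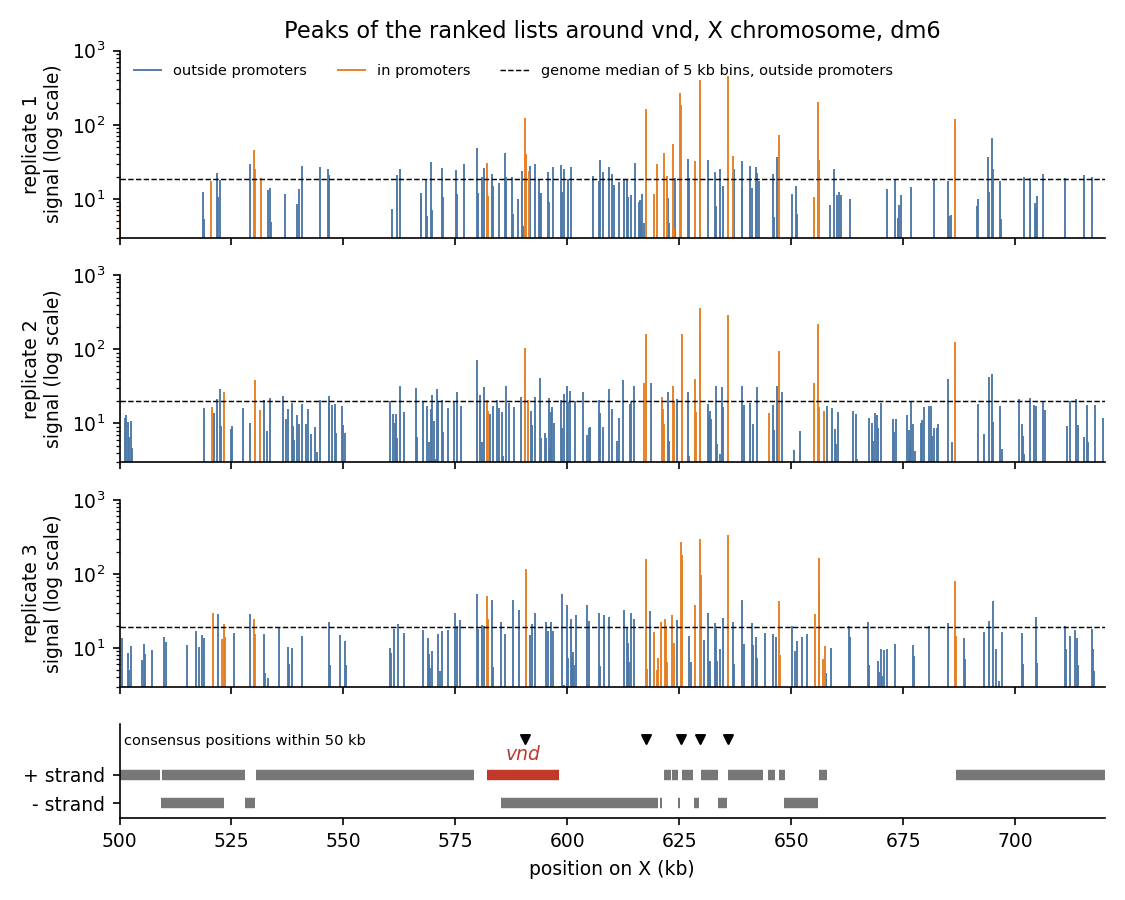
Signal of the peaks in each replicate's ranked list (log axis, the authors' units) along 500 to 720 kb of the X chromosome, with peaks in promoters in orange and other peaks in blue, the genome median of 5 kb bins as a dashed line, genes by strand, and the 5 consensus positions within 50 kb of vnd as triangles. The strongest peaks were in promoters to the right of vnd, and bins above the dashed line were frequent around vnd in all 3 replicates, 20, 22 and 16 of 24.

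The other fixed genes of the ventral neuroectoderm had little signal that passed the filter. No consensus position lay in the territory of ind or Dr, the homeobox genes of the intermediate and dorsal columns, or of the proneural genes ac, sc and l(1)sc, and none of these 5 had a region in any single replicate. The territory of Egfr (2R, 21522420 to 21559977) held 1 position with a rank of 78.2, but it lay 14 bp from the TSS of the neighbouring gene CG10494, named here for that reason.

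To ask whether the replicates found the same places, each list was compared with the others. On average 79.4% ± 5.02 (SD over 6 ordered pairs) of the peaks of one replicate overlapped a peak of another. The share ranged from 74.7% of replicate 1 in replicate 2 to 87.2% of replicate 2 in replicate 1. Random placement gave 0.929% and 1.11% for these pairs, and no placement reached the observed share in any pair (one-sided permutation p = 0.001, the smallest possible). The union of the 3 lists held 2608 regions, of which 1407 (53.9%) had a peak from all 3 replicates, 469 from 2 and 732 from 1. Within the 1407 consensus regions the strongest summits of the replicates lay a median of 28 bp apart, and the regions had a median width of 402 bp. Consensus regions had a median rank of 65.5 and single-replicate regions one of 18.97.

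The authors' joint lists were larger. Their thresholded lists held 3825, 2874, 2605 and 2971 peaks, the last of them being the list named conservative. Between 40.7% and 60.4% of their regions overlapped a consensus region, and each list contained at least 99.8% of the consensus regions. Across peaks with a global IDR of 0.01 or less, the signals of the 2 members compared in a joint ranked list had a Spearman correlation of 0.834 to 0.859, and those in the single replicates' own ranked lists one of 0.789 to 0.793. The IDR itself selects peaks on which the members agree; over all peaks the correlations were 0.218 to 0.321 in the joint lists and 0.162 to 0.194 in the single replicates' lists. These are correlations across peaks, which are not independent replicates.

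Peaks lay at gene starts. Of the 1407 consensus positions, 1279 (90.9%, 95% Wilson interval 89.3 to 92.3) were in promoters, against 11.5% of random positions, a ratio of 7.90. Within the promoters the median position was 47 bp upstream of the nearest TSS, and 81.4% were within 100 bp of it. Introns held 59 positions (4.19% against 39.4% at random), intergenic sequence 63 (4.48% against 29.7%) and 3′ UTRs 6 (0.426% against 4.58%), while coding exons and 5′ UTRs outside promoters held 0. All 6 classes differed from random placement (two-sided permutation, adjusted p = 0.002, the smallest possible). The 6 shares are parts of the same total. The low shares outside promoters therefore follow in part from the promoter share and are not separate results. In the replicates' own regions the promoter share was 83.4% ± 1.86 (SD, n = 3).

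**Figure D2:**
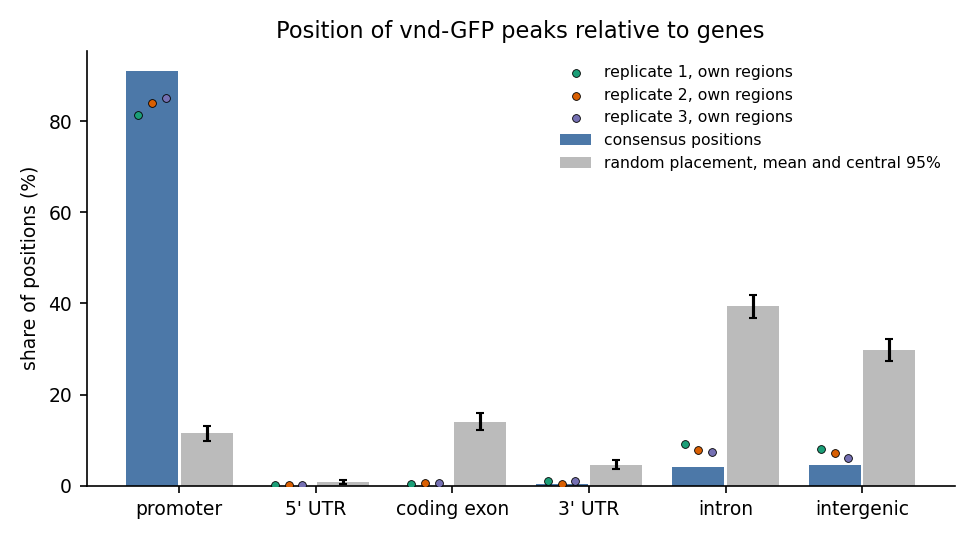
Share of positions (%) by gene feature for the 1407 consensus positions (blue bars), for each replicate's own regions (points) and for 1000 random placements (grey bars, mean with the central 95%). The promoter share was 90.9% at consensus positions and 11.5% at random positions, and every replicate lay between 81.4% and 85.0%.

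The 15 regions of highest rank were all in promoters, each within 102 bp of a TSS. The first was at MESK2 (2R 21502011, 86 bp upstream of the TSS, rank 100). It was followed by Rpn6 (2R 14752362), a proteasome subunit gene, RpL32 (3R 30046246), a ribosomal protein gene, RhoGAP93B (3R 21097896) and CG11857 (3R 25258836). The others were at Mic26-27, Pp2A-29B, CG8613, Creld, EndoGI, Capr, mi, Ube3a, Sry-alpha and Pym. All 15 had ranks of at least 99.2. Within 50 bp of the position, 2 of the 15 (Creld and Pym) had TATCGATA and 0 had CAAGTG. The genes with the most positions in their territory were CG14442, mahe, Ubr3 and Pu, with 4 each, followed by genes with 3, among them CG17292, tud and Pp2A-29B. For CG14442, mahe, Ubr3, Pu and CG17292, 1, 0, 1, 0 and 1 of these positions, in that order, were in a promoter of the gene itself.

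To ask which gene groups were bound, the fixed lists were compared with random lists of the same size and territory length. Of 13968 protein coding genes, 3598 (25.8%) had a consensus position in their territory. Of the 18 lists, 1 was bound more often than random lists and 1 less often after adjustment. Of 85 ribosomal protein genes, 43 were bound against 19.2 expected, a ratio of 2.24 (permutation p = 0.0002, adjusted p = 0.0018), and in the replicates 50.3 ± 1.15 (SD, n = 3) were. In 31 of them the position was in a promoter of the gene itself. The members of highest rank were RpL32 (99.9), RpS13 (99.7), RpL36 (98.5) and RpS2 (97.4); the RpS13 region was nearest to the TSS of Pp2A-29B. Chemoreceptor genes (odorant, gustatory and ionotropic receptors) were bound less often, with 11 of 179 against 45.9 expected, a ratio of 0.239 (permutation p = 0.0002, adjusted p = 0.0018), and 15.7 ± 2.08 (SD, n = 3) in the replicates. None of the 11 had a position in its own promoter; those of Ir93a, Or2a, Ir60e and Or9a, which had the highest ranks, were nearest to other genes' TSSs.

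No list on the nervous system and its patterning passed the adjusted test. In ventral neuroectoderm patterning 1 of 12 genes, vnd, was bound against 3.54 expected (permutation adjusted p = 0.399), and in EGFR signalling 4 of 15 against 4.49 (permutation adjusted p = 1), among them the ligand genes Krn (rank 95.1, own promoter) and spi (80.8, nearest to the TSS of Pmvk). Of 16 proneural and neuroblast genes 3 were bound, brat (86.0) at its own promoter, and erm and insc at the promoters of Der-1 and sktl. None of the 7 temporal neuroblast factors, hb and Kr among them, had a position. With 2.08 expected, 0 bound gave a permutation p of 0.168, so a lower share could not have been called in this list. Of 28 neuronal identity factors 3 were bound, kn, Lim3 and Ptx1, against 8.10 expected (permutation p = 0.0426, adjusted p = 0.153). It passed in 2 of 13 alternatives, over which the permutation adjusted p ran from 0.0202 to 0.738. The highest ranked position of kn lay in the promoter of BEAF-32, with 0 in its own promoter, and the Lim3 position was in an intron. Of 20 genes of neuronal function 1, nSyb, was bound against 5.81 expected (permutation p = 0.0188, adjusted p = 0.0846), and its position was in the promoter of the neighbouring Bgb. The list passed in 5 of 13 alternatives, with permutation adjusted p from 0.0036 to 0.5615. Axon guidance had 7 of 21 bound against 5.84 expected, among them fra (91.1), Dscam1 (80.4), Ptp10D (75) and PlexB (71.9). Glia had 2 of 10, wrapper at the promoter of Rtf1 and loco at its own. The permutation adjusted p was 0.812 for both the axon guidance and the glia list.

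The remaining developmental lists gave similar counts. Of 20 segmentation genes 1, hh, was bound against 5.81 expected (permutation p = 0.0162, adjusted p = 0.0846), and its position was 4 bp from the TSS of the neighbouring CG31457; the list passed in 4 of 13 alternatives, with permutation adjusted p from 0.0045 to 0.5615. Of 8 Hox genes 1, Ubx, was bound, at the promoter of modSP. Of 14 NK homeobox genes 2 were bound, tin and vnd. Notch signalling had 4 of 17, mam (82.0) and Su(H) (69.3) at their own promoters and E(spl)m8-HLH and neur at those of gro and hyx. Mesoderm and muscle had 2 of 16, Mef2 at its own promoter and Tm1 at that of Cp190, dorsal ectoderm 2 of 11, Ance and tld at the promoters of Smg5 and asp, and endoderm and gut 0 of 9. The germline list had 5 of 11 against 3.49 expected, bgcn (99.2), piwi (95.3), bam (94.8) and tud (48.5) being the highest. The first 3 of these positions lay at the promoters of Pym, TTLL4A and Nup358, while tud and the remaining bound member, gcl, had a position in their own promoters. The permutation adjusted p of these lists other than segmentation lay between 0.241 and 1.

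**Figure D3:**
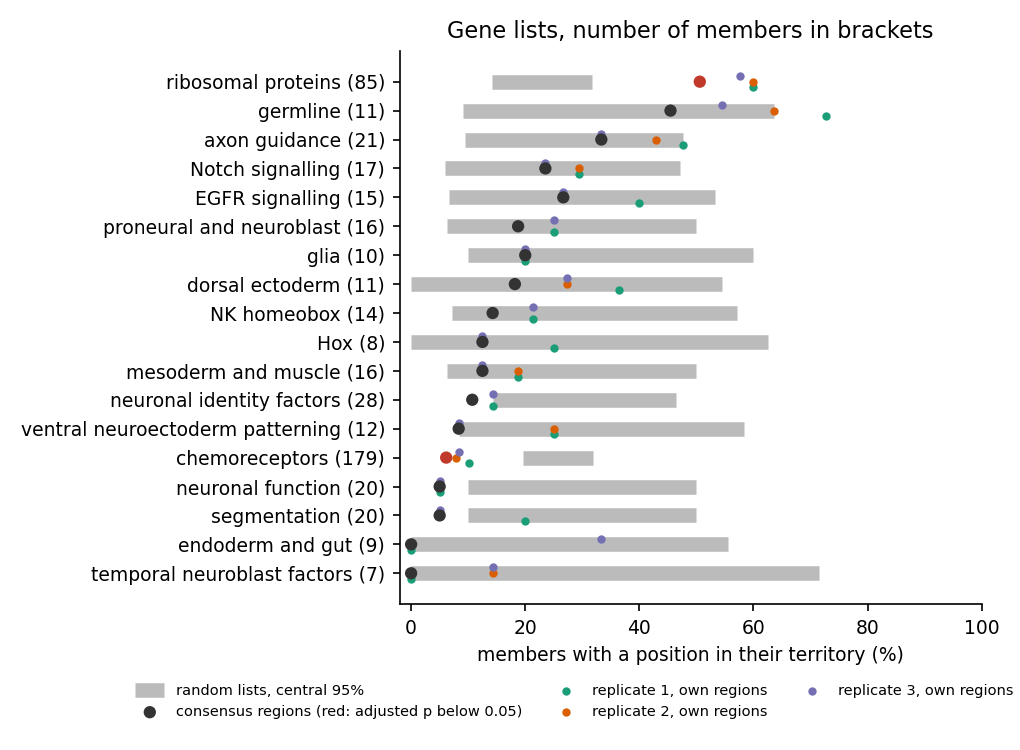
Share of each list's members (%) with a position in their territory, for the consensus regions (large points, red where the adjusted p was below 0.05), for each replicate's own regions (small points) and for random lists of matched territory length (grey, central 95%). Ribosomal proteins lay above and chemoreceptors below the range of random lists; neuronal identity factors, neuronal function and segmentation also lay below it but did not pass the adjustment.

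To ask whether the tagged protein's own site lay at the summits, CAAGTG was counted. It was within 50 bp of 71 of 1407 consensus positions (5.05%, 95% Wilson interval 4.02 to 6.32), against 93 upstream and 82 downstream windows (exact McNemar p = 0.0882 against upstream, adjusted p = 0.128). The ratio of the centre to the mean of the flanks was 0.811. In the replicates' own regions the share was 5.65% ± 0.248 at the centre and 6.01% ± 0.156 in the flanks (SD, n = 3). By ratio, CAAGTG was number 1123 of 2080 6-mers. CAAGTG was less frequent at regions in 3 replicates than at the 732 regions in 1 replicate (5.05% against 7.92%, Fisher's exact adjusted p = 0.0288); this call was lost without replicate 1 (adjusted p = 0.152) and without replicate 2 (0.236) in the same exact test on regions in 2 against 1 replicate. Neither the highest against the lowest quartile by rank (3.41% against 6.82%, Fisher's exact adjusted p = 0.0877) nor promoters against other positions (4.93% against 6.25%, Fisher's exact adjusted p = 0.523) passed the test.

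Of the comparison motifs, TATCGATA, the DNA replication-related element of housekeeping promoters, stood at 368 positions (26.2%, 95% Wilson interval 23.9 to 28.5), against 7 upstream and 6 downstream windows. The ratio was 56.6 (exact McNemar adjusted p = 2.66e-99). In the replicates' own regions its share was 22.7% ± 0.636 at the centre and 0.474% ± 0.0280 in the flanks (SD, n = 3). CAGGTAG and ACAATG were less frequent at the centre than in the upstream window, at lower coordinates (ratios 0.214 and 0.624, exact McNemar adjusted p = 0.0264 and 0.0347). TAATTA, GAGAGA and CAGCTG did not pass the test (ratios 1.39, 0.764 and 1.08). Among all 6-mers the lowest p belonged to TATCGA, at 818 positions (58.1%, 3.91% in flanks), ATCGAT at 739 and CGATAG at 695. TATCGATA was more frequent in promoters than at other positions (27.9% against 8.59%, Fisher's exact adjusted p = 4.11e-07) and at regions in 3 replicates than in 1 (26.2% against 9.43%, Fisher's exact adjusted p = 5.72e-21), and did not differ detectably between the highest and lowest quartile by rank (23.0% against 24.7%, Fisher's exact adjusted p = 0.658). These 3 comparisons for TATCGATA were added after seeing the data.

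**Figure D4:**
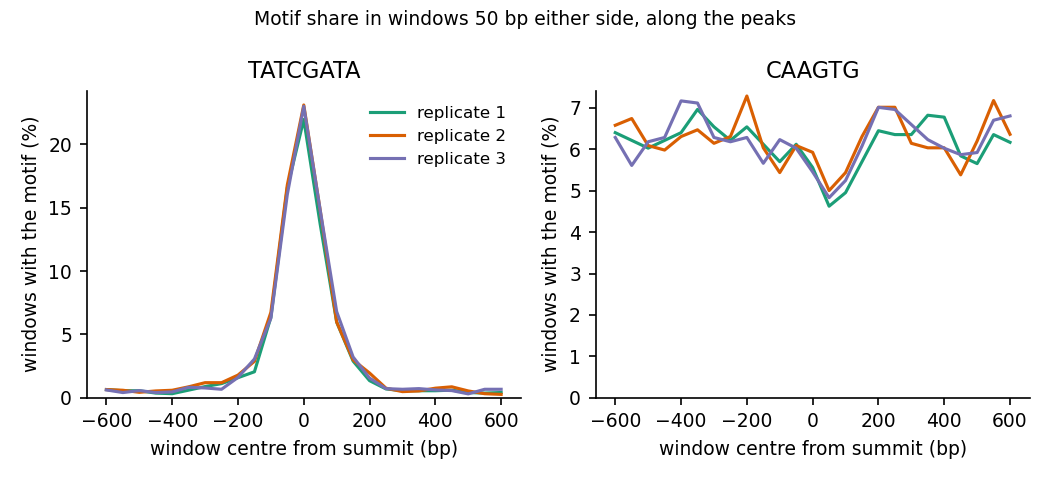
Share of windows (%) reaching 50 bp either side that held TATCGATA (left) or CAAGTG (right), by distance of the window centre from the position (bp), for each replicate's own regions. TATCGATA reached between 21.96% and 23.1% at the centre in the 3 replicates, where CAAGTG was at 5.45% to 5.93%.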

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

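The tests of the vnd-GFP line, the core elements, base composition, the weaker peaks and the wider window were chosen after the patterns were seen; the tests of the breadth of the vnd rise and of NK-2 sites in the locus were set before their values were seen. The report's comparisons leave out peaks off the main arms. Thresholded peaks on other sequences numbered 24 in replicate 1, 20 in replicate 2 and 7 in replicate 3, each above the count of 3 set for a closer look. They lay on 38 sequences, of which 2 had a peak in all 3 replicates. By their names, all of these sequences are assigned to X without a place on the arm.

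The first pattern is the set of peaks at TATCGATA promoters without the NK-2 site. Signal around vnd in peaks outside promoters and away from CGATA was above that of at least 99.8% of genes in each replicate. The rise around vnd was seen before this test was chosen. Whether the region is raised in libraries of other lines was not tested. The value therefore cannot decide whether the flies were the vnd-GFP line. Promoters with a position within 100 bp of a TSS held TATCGATA within 100 bp of that TSS in 40.4% of cases. Around the outermost TSS of genes without a promoter position the share was 4.14%. The odds ratio was 15.7 (exact interval 13.5 to 18.2). Another core element of constitutive promoters, GGTCACAC, had an odds ratio of 1.304 (1.04 to 1.62). CAAGTG, the core of the NK-2 class site, was at 10.1% of promoters with a position and 12.98% of those without. Its odds ratio was 0.753 (0.614 to 0.917), and that of CAGCTG was 1.104 (0.927 to 1.308). TATCGATA thus marked these promoters far more than GGTCACAC did. Genes were counted, so both genes of a pair that shares a promoter could count the same element, and the exact intervals can be too narrow. The choice of TSS also differed between genes with and without a position. These values cannot decide whether active promoters were taken up alike, since the promoters without a position were not sorted by activity. For base composition, TATCGA was set against 457 6-mers with as many G and C bases, leaving out those sharing 4 letters in a row with TATCGATA. That 0 of them had a centre to flank ratio as high (14.6) follows from picking TATCGA by its lowest p. The gap does not follow from it: the highest ratio among them was 3.66. The number of G and C bases alone therefore did not give the ratio of TATCGA. What also stays open is whether a protein at this element was precipitated with the tagged protein or by the antibody alone. Untagged embryos would be needed for that. No biological explanation was tested, as there is 1 group.

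The second pattern is the raised signal around vnd outside promoters. Extra copies of the locus carried by the tag construct would raise it broadly, and the lower quartile of the 5 kb bins within 50 kb of vnd was above that of 99.9% and 99.7% of genes in replicates 1 and 2 but 83.2% in replicate 3, short of the bound of 95% set for all 3. Binding at NK-2 sites in the locus would put CAAGTG at more of its summits than at summits of the same signal elsewhere. It was at 7, 13 and 9 summits against 7.20, 9.78 and 7.097 expected (highest one-sided permutation p = 0.576), with upper bounds of the ratio of 2.00, 2.27 and 2.41. Neither explanation could be excluded, since replicate 3 fell between the set bounds and the CAAGTG counts were too few.

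The third pattern is that CAAGTG was no more common at consensus positions than in the flanks. A window that missed sites beside the summit is argued against by windows reaching 100 bp either side, where the ratio of centre to flank was 0.798 (bootstrap interval 0.655 to 0.955). NK-2 sites might instead lie at weaker peaks outside promoters. At the 4000 such summits per replicate that follow the strongest 1000, CAAGTG stood at 8.40%, 8.03% and 7.67% against 6.03%, 6.66% and 6.23% in the flanks. Its ratio was above that of 97.8%, 73.4% and 86.6% of 6-mers with as many G and C bases, so 1 replicate passed 95% and the others did not, and the explanation stays open.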

How the results depend on the processing

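The IDR filter of 0.001, the TATCGATA settings, the set without TATCGATA and leaving out replicates in the motif classes were chosen after seeing the data; the other alternatives were planned. The overlap between replicates, the promoter share and the TATCGATA excess kept their direction and side of the threshold under each alternative run. Overlap lay between 66.4% and 83.7%, the promoter share between 78.1% and 94.6%, and the TATCGATA ratio between 37.0 and 92. Ribosomal proteins and chemoreceptors passed in 13 of 13 alternatives, with ratios of 1.45 to 3.76 and 0 to 0.498. The alternative limited to genes with a ranked peak in the promoter, in any replicate, kept 12554 of 13968 genes. It therefore differed little from the full set of genes and did not sort them by promoter activity. For values that changed, the cause was not tested except where the setting itself sets the count. Peaks above each list's median signal left 1079 peaks per replicate and 813 consensus regions, and the authors' conservative list gave 2668 regions and 9 positions near vnd, where 20 kb gave 2. Without 1 replicate, peaks per replicate were 2045 to 2254, consensus regions 1479 to 1613 and positions near vnd 4 to 6. The count of gene lists past the threshold was 5 with regions in at least 2 replicates and 5 with the conservative list, 3 with lists and random lists both limited to genes with a ranked peak in the promoter, where neuronal function was added with its 1 bound member left out, and 2 to 4 without 1 replicate (4 without replicate 2 and 4 without replicate 3, where segmentation and neuronal function were added; neuronal identity factors joined them in both sets with 5).

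CAAGTG ratios below 1 passed the exact McNemar threshold without adjustment at an IDR of 0.001 (0.687) and in windows reaching 100 bp either side (0.798). With flanks at 1000 bp (0.798) the ratio passed as well. The main call was adjusted over the 7 motifs and these alternatives were not, so they are less strict. In the conservative list the ratio was 1.06, on the other side of 1 (exact McNemar p = 0.298). The CAAGTG odds ratio between regions in all replicates and in 1 lay at 0.546 to 0.805 without 1 replicate. The TATCGATA odds ratio between the highest and lowest quartile, not past the threshold, was 1.14 in those wider windows and 1.05 to 1.17 without 1 replicate. Of 234 values over all lists and alternatives, 15 crossed their random mean, each of a list not past the threshold. EGFR signalling had 10 bound in the conservative list and 4 above the median signal, at an IDR of 0.001, with unmatched random lists and without regions holding TATCGATA. Notch signalling had 7 in the conservative list, 2 by nearest TSS, 3 within 1 kb of a TSS and 11 within 20 kb. Dorsal ectoderm had 5 in the conservative list and 2 above the median signal, glia 2 above the median signal, NK homeobox 2 by nearest TSS and 2 within 1 kb, and axon guidance 10 within 20 kb. Of 66 named genes, 12 lost their positions above the median signal and 6 at an IDR of 0.001, and 0 did in the other sets. No joint list was run as a list of pooled replicates, since no name says which of them that would be. No paired analysis was possible because there is 1 group. Without read counts, depth sets no stated limit here.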

Other observations

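All counts in this part were chosen after seeing the data. A second set of places, outside promoters, was near tRNA genes. Of the 128 consensus positions outside promoters of protein coding genes, 33 (25.8%) were within 200 bp of a tRNA gene, where random placement outside promoters gave a mean of 0.129 and at most 2 (one-sided permutation p = 0.001, the smallest possible). With promoters included, 38 positions lay near a tRNA gene, and 52 of the 290 annotated tRNA genes had one. In the replicates' own regions outside promoters the counts were 88 of 398, 55 of 296 and 43 of 288. None of the 33 had TATCGATA within 50 bp (0 of 33), against 11 of the other 95 positions, and 13 of the 33 had GGTTCGA, part of the internal promoter (B box) of tRNA genes. Copies of a tRNA gene can share reads, so single members are uncertain.

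Gene families were also compared by symbol; RpS, RpL, Gr, Or and Ir are part of lists tested above. Of 67 families of at least 10 genes that share the letters of their symbol, 5 were bound more often and 8 less often than random lists of matched territory length (permutation, adjusted p below 0.05). More often bound were genes of the large subunit of the mitochondrial ribosome (mRpL, 27 of 47 against 9.04 expected), cytoplasmic small subunit proteins (RpS, 23 of 38 against 8.59), Rab GTPases (18 of 31 against 8.54), RhoGAP genes (10 of 13 against 4.003) and RNA polymerase subunits (Polr, 14 of 30 against 7.02). Less often bound were cuticle proteins (Cpr, 1 of 70 against 15.4), the Osi family (0 of 25 against 6.43), UDP-glycosyltransferases (Ugt, 2 of 35 against 9.47), serpins (Spn, 1 of 27 against 7.1003), the Gr, Or and Ir receptors already counted, and histone genes (His, 2 bound against 16.7). Histone genes sit in near-identical repeats whose reads cannot be placed singly, so their count is uncertain. In the families bound more often, 16 mRpL, 17 RpS, 13 Rab, 4 RhoGAP and 6 Polr genes had a position in their own promoter. RpL (18 of 50 against 11.3, permutation adjusted p = 0.1395) and mRpS (7 of 26 against 4.90, 0.675) did not pass. The permutation adjusted p of the 13 families that passed lay between 0.0027 and 0.0412. Neighbouring members of a family can share a position or lack it together, while random lists drew genes singly. For families with such members these p-values can be too small.

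Promoters shared by neighbouring genes were frequent among the bound ones. Of 1279 promoter positions, 553 (43.2%) had start sites of 2 different genes pointing away from each other within 500 bp, against 21.8% of the 12084 genes without a promoter position (odds ratio 2.73, Fisher's exact p = 1.60e-58). The share depends on how the unbound starts were chosen, here the outermost start site of each gene. The measures also differ: windows were centred on the position for bound promoters and on a start site for unbound genes. Positions were counted among the bound, and genes, so both genes of a pair, among the unbound. The odds ratio and its p are therefore not a like for like comparison.

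In 3 of the 4 joint ranked lists, each member's peaks matched those of a single replicate's ranked list by position and signal in 56.1% to 83.1% of cases. In the remaining list no peak did.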
